A study of Mus musculus with 20 samples.

How the data were processed

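The series holds 20 libraries of mouse B cell DNA made by high-throughput genome-wide translocation sequencing, in which a biotinylated primer beside a known break (the bait) is extended into whatever sequence that break was joined to (the prey). Of these, 8 libraries map signal joints and 12 map class switch junctions. Signal joints are the joints between a pair of recombination signal ends that the RAG recombinase cuts free. They were read from an integrated inversion substrate, pMX-INV, in v-abl transformed B cells held for 3 days in 3 µM STI571, a kinase inhibitor that arrests these cells in G1 and switches on RAG. Class switch junctions were read from a bait in Sμ, the donor switch region, in splenic B cells depleted of CD43+ cells and cultured for 4 days with 1 µg/mL anti-CD40 and 20 ng/mL IL-4, which direct switching to Sγ1 and Sε. Per the labels' protocols, uncut germline product was removed with a restriction enzyme in both assays.

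Genotypes were taken from the labels. Ku70 ΔSAP lacks amino acids 558 to 608 of Ku70, the DNA-end binding protein of non-homologous end joining, and DNA-PKcs is the kinase that Ku recruits to ends. The signal joint groups are wild type (WT), ΔSAP, DNA-PKcs−/− and the double mutant, with 2 libraries each. The class switch groups are WT (2 libraries), ΔSAP (3), HL (2), DNA-PKcs−/− HL (2) and double-mutant HL (3). HL stands for a pair of alleles that the labels abbreviate and do not spell out. The labels give 1 DNA-PKcs−/− signal joint library (replicate 2) as a pool of 3 biological replicates and 1 ΔSAP class switch library (replicate 3) as a pool of 2. For the other libraries nothing states that replicates came from separate cultures or animals, so p-values measure the spread between these samples, which may be technical.

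The deposited files are workbook sheets with 1 line per junction or with counts of junctions. The submitters' processing notes name Bowtie2, with no version, and the builds mm9 and mm10 without saying which file used which. The class switch positions are therefore given as the files print them, on chromosome 12, with the build not stated. The columns used are positions, sequences, counts and shares, with no normalization. The workbooks that pool the libraries of a genotype, and the sheets of large insertions, of mutated baits and of single junctions outside IgH, were not used here.

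For signal joints, the authors deposited all junctions of a library, those on the substrate, a list they call bona fide and a list of deletions. Their deletion lists place the bait signal end at substrate position 1946 and the prey signal end at 2815, and all 7074 deletion lines read carry that bait position. The most frequent joint aligns to 1948 and 2817, because both alignments extend 2 bases past the ends. A joint was called precise when no base was missing from either end. Among precise joints, those that did not align as the most frequent joint were counted as carrying inserted bases. That call rests on the alignment ends alone. Inserted sequence was read only for part of these joints in 1 WT and 1 double-mutant library. Loss was summed over both ends, and a long deletion was one of more than 20 bases.

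The authors' list proved to be a window of positions, and the window was not the same in all libraries. Joints with a bait end from 1849 to 1953 were kept in 3 libraries (WT replicate 1 and both ΔSAP libraries), and joints from 1741 to 1948 in the other 5, with prey ends from 1949 to 2817 on the minus strand throughout. The bait loss is thereby limited to 97 bases in the first set and to 205 bases in the second. The rule recovered every joint of the authors' list in 7 libraries, and 27890 of 27891 in WT replicate 1. The main values use the authors' window of each library. After this was seen in the files, 1 wide window and 1 narrow window for all libraries were added as alternatives. The deletion lists follow the wide window in every library, including the 3 whose bona fide list is narrow. They hold the joints that stop at or before both signal ends, and so include joints with no loss. Microhomology at signal joints and insertions at joints with a loss were not computed, since the sheets used hold no read coordinates.

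For class switch junctions, the authors deposited counts of junctions by region and by the overlap or gap between bait and prey, lists of positions, and a share they call distal. From these counts the shares of Sμ, Sγ1, Sε, other IgH sequence and sequence outside IgH were computed over all junctions of a library, and within each switch region the shares with microhomology, with a direct join and with an insertion. The authors' distal shares were matched to positions. A distal junction lies at or below 114665100 in Sμ, 114566000 in Sγ1 and 114513000 in Sε, where lower coordinates lie further along the direction of IgH transcription. Orientation was taken from the strand of the prey, and the minus strand is the deletional orientation. Bait mismatches were counted per 10000 aligned bait bases from the alignment strings, in the libraries whose sheets hold them.

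Signal joint libraries held from 679 to 37949 junctions, of which 128 to 27890 were signal joints. Class switch libraries held from 2571 to 14952 junctions. Junctions are PCR products read without molecular identifiers in the sheets used, so intervals (Wilson, 95%) cover counting error only. Replicates of each group were compared by a chi-square test. Every signal joint pair differed over the 20 most frequent joints and every class switch pair over the 5 regions, so no library was counted as a repeat of another. Over the 20 most frequent Sγ1 positions no class switch pair was set apart, with p from 0.254 to 0.978.

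The library was the unit of every test. Group means were compared by a two-sided exact permutation test over all splits of the libraries, with Benjamini-Hochberg adjustment over the measures and comparisons of 1 result. The smallest p is 0.333 for 2 libraries against 2, 0.1 for 2 against 3, 0.0286 for 4 against 4 and 0.0476 for 5 against 2. The effect of ΔSAP was also tested over both DNA-PKcs states, permuting within each state. That test can reach 0.01 in the class switch libraries, but only 0.0556 in the signal joint libraries, where the plan had taken it to reach 0.05. Fisher's exact test on junction numbers compares libraries, not genotypes. The statistics were tested on simulated data. Of 2000 null comparisons per design, at most 5.2% fell under 0.05, and shifts of 5 SD were called in 99.7% of comparisons of 4 against 4 and in 99.25% of comparisons of 5 against 2. For 3 against 2 in each of 2 strata 100% were called. For 2 against 2, 3 against 2, and 2 against 2 in each of 2 strata the share was 0%, since those designs cannot reach 0.05. Python 3.11.15, numpy 2.4.6, scipy 1.17.1 and matplotlib 3.10.9 were used.

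The alternatives were the joints counted, each distinct joint once, pooled libraries, each library left out, the replicate number as a block, medians, other size limits, other denominators, other definitions of microhomology and insertion, and region edges moved by 2 kb. They were fixed before the data were examined, except for both bait windows, the authors' deletion lists and the interaction under other choices of joints. Over all substrate joints, the precise share was taken over substrate junctions of both strands, and the other measures over minus-strand joints alone. The rule for named joints took the 5 most frequent joints with a loss, and the 5 most frequent sizes, of each genotype. A number that several libraries share in their deposited names was taken as a run tag. It places the signal joint libraries in 4 runs and the class switch libraries in 2. That this tag marks a sequencing run is an assumption.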

Results

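Junctions of V(D)J recombination and of class switch recombination were mapped in B cells that lacked the SAP domain of Ku70, DNA-PKcs, or both. Signal joint libraries of DNA-PKcs-proficient cells held 14244 to 37949 junctions, and those of DNA-PKcs-deficient cells 679 to 7459. Signal joints made up 70.9% ± 3.66 of all junctions in WT, 77.3% ± 0.498 in ΔSAP, 12.8% ± 8.51 in DNA-PKcs−/− and 28.9% ± 0.0418 in the double mutant (SD, n = 2 each). The 2 DNA-PKcs−/− libraries thus rest on 377 and 128 signal joints, against 2119 and 2161 in the double mutant and at least 10961 in each proficient library. Class switch libraries held 10676 to 14952 junctions in WT and ΔSAP and 2571 to 4672 on the HL background. Over both assays 129 comparisons were tested, 15 had an unadjusted p under 0.05 and 0 had an adjusted p under 0.05 by the exact permutation test with Benjamini-Hochberg adjustment. That 0 was fixed by the number of libraries and tests: with every test at its smallest p, the adjusted p could not go below 0.111 for a signal joint result, 0.06 for class switch regions, structure and position, or 0.07 for bait mismatches. The adjusted p thus separates nothing here, and differences are given as values with the spread between libraries. In signal joints that spread is not alike in kind. Both ΔSAP libraries shared a run tag, as did both double-mutant libraries, while the WT and the DNA-PKcs−/− libraries each carried different ones.

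The first comparison asks whether loss of the Ku70 SAP domain alone alters signal joints. Nearly all joints kept both signal ends in either genotype, 94.9% ± 0.654 in WT and 93.4% ± 0.211 in ΔSAP (SD, n = 2 each), and both ΔSAP libraries lay below both WT libraries. The mean loss over all joints was 1.59 ± 1.56 bases in WT and 2.13 ± 1.42 bases in ΔSAP. Among the joints that lost bases, the same sizes led in both genotypes, losses of 1 base making up 27.0% in WT and 27.8% in ΔSAP, followed by losses of 2, 3, 4 and 6 bases. The most frequent single joint with a loss kept the whole bait end and lacked 1 base of the prey end, with 313 joints in WT and 235 in ΔSAP. Long deletions were 0.552% ± 0.496 of WT joints and 0.650% ± 0.300 of ΔSAP joints. By the alignment ends, 15.3% ± 2.24 and 12.6% ± 1.67 of precise joints were counted as carrying inserted bases.

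For the precise share the exact permutation p was 0.333, the smallest that 2 libraries against 2 allow. Fisher's exact test, which compares libraries and not genotypes, gave p from 2.69e-16 to 0.00621 for the 4 pairs. The difference in precise share of -1.48 percentage points was -1.88 with 1 wide bait window for all libraries and -1.63 with 1 narrow window. It was -0.483 over all substrate joints of both strands and -0.666 with losses of at most 2 bases also called precise. When each distinct joint was counted once, it turned to 4.68. Precise joints occupy only 4 to 18 positions per library and joints with a loss 34 to 176, so a count of distinct joints mostly measures how many different losses were sampled, and it says little on how frequent precise joints are. The difference in mean loss over all joints was 0.538 bases with the authors' windows, 3.68 with 1 wide window, 1.49 with 1 narrow window and 8.28 over all substrate joints, and lay between -0.568 and 1.64 with 1 library left out. Over joints with a loss, ΔSAP minus WT depended on the window, which for WT replicate 2 is wide and for the other 3 libraries narrow. It was 2.59 bases with these windows, 38.2 with 1 wide window, 19.2 with 1 narrow window and 46.1 over all substrate joints (exact permutation p = 0.333, the smallest possible, under the last 3 choices), and turned to -1.55 with deletions over 200 bases left out and to -4.55 over distinct joints. The authors' own deletion lists apply the wide window to all libraries, and their lines with a loss averaged 86.3 ± 18.8 bases in ΔSAP and 53.2 ± 0.293 in WT (SD, n = 2 each), both ΔSAP libraries above both WT libraries (exact permutation p = 0.333). Over every line of these lists, 52.1% of which in WT and 30.8% in ΔSAP lost nothing, the means were 25.7 and 25.3 bases in the WT libraries and 51.6 and 67.5 in the ΔSAP libraries. Likewise, that in long deletions (0.0986 percentage points) lay between -0.252 and 0.449 and was 0.539 with the wide window, 0.271 with the narrow one and -1.08 over all substrate joints, and that in insertions (-2.70) between -4.28 and -1.12. No run tag was shared by both genotypes.

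The comparison of DNA-PKcs-deficient with proficient cells asks what the kinase contributes to signal joints. Precise joints were 73.8% ± 7.84 of signal joints in the 4 deficient libraries and 94.1% ± 0.941 in the 4 proficient ones, a difference of -20.3 percentage points, and every deficient library lay below every proficient one. The mean loss over all joints was 53.5 ± 36.8 bases against 1.86 ± 1.26. Long deletions were 12.1% ± 8.78 of signal joints against 0.601% ± 0.340. In DNA-PKcs−/− the most frequent joints with a loss included a prey end short of 4 bases (9 of 151 joints) and 3 recurrent joints that lacked 743, 771 and 806 bases. Each of these 3 lost more than 97 bases from the bait end, and the one that lacked 771 bases was also the fifth most frequent joint with a loss in the double mutant (30 of 865).

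The exact permutation p was 0.0286 for each of these 3 measures, the smallest that 4 libraries against 4 allow, with an adjusted p of 0.114. With 1 narrow bait window for all libraries, which takes out joints with a bait loss over 97 bases, the difference in mean loss over all joints was 4.36 bases in place of 51.6 and that in long deletions 4.41 percentage points in place of 11.5. With 1 wide window they were 48.7 bases and 11.02 points, and the exact permutation p stayed at 0.0286 with either window. Over all substrate joints they were 111.6 bases (exact permutation p = 0.0286) and 12.5 points (exact permutation p = 0.229). Over distinct joints they were 107.0 bases and 20.1 points, and with deletions over 200 bases left out the difference in mean loss was 4.93 bases. Without the pooled DNA-PKcs−/− library the difference in mean loss was 33.8 bases, and leaving out any 1 proficient library took its exact permutation p, and that of long deletions, to 0.0857. Over all substrate joints of both strands the difference in precise share was -33.7 percentage points, and over distinct joints, with the limit given above, -1.18. Over joints with a loss alone, the mean loss differed by 158.5 bases with the authors' windows (exact permutation p = 0.0286). That difference depended on the window: 118.3 bases with the wide one (exact permutation p = 0.0286) and 4.69 with the narrow one (exact permutation p = 0.486). Over all substrate joints it was 114.1 bases (exact permutation p = 0.0571). Within the run that held WT replicate 2, DNA-PKcs−/− replicate 1 and both double-mutant libraries, the precise share was 94.4%, 72.4% and 79.8%.

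The next comparison asks what the SAP deletion does to the joints that form without DNA-PKcs. Double-mutant joints were precise in 79.8% ± 0.149 of cases, against 67.8% ± 6.46 in DNA-PKcs−/− (SD, n = 2 each). Long deletions were 5.17% ± 0.435 against 19.0% ± 6.26, and the mean loss was 29.1 ± 1.05 bases against 77.9 ± 41.1. The median loss of joints with a loss was 3 and 4 bases in the double-mutant libraries, close to the 3 bases of every proficient library, and 24 and 117 bases in the DNA-PKcs−/− libraries. Over the joints of both libraries of a genotype, losses of 1 base were 30.5% of the double mutant's joints with a loss and 5.96% of those in DNA-PKcs−/−. By the alignment ends, 38.0% ± 4.14 of precise joints were counted as carrying inserted bases in the double mutant and 7.98% ± 0.931 in DNA-PKcs−/−. The former lay above and the latter below each WT and ΔSAP library, as the plot of signal joints per library shows. No inserted sequence was read in a DNA-PKcs−/− library.

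**Figure D1:**
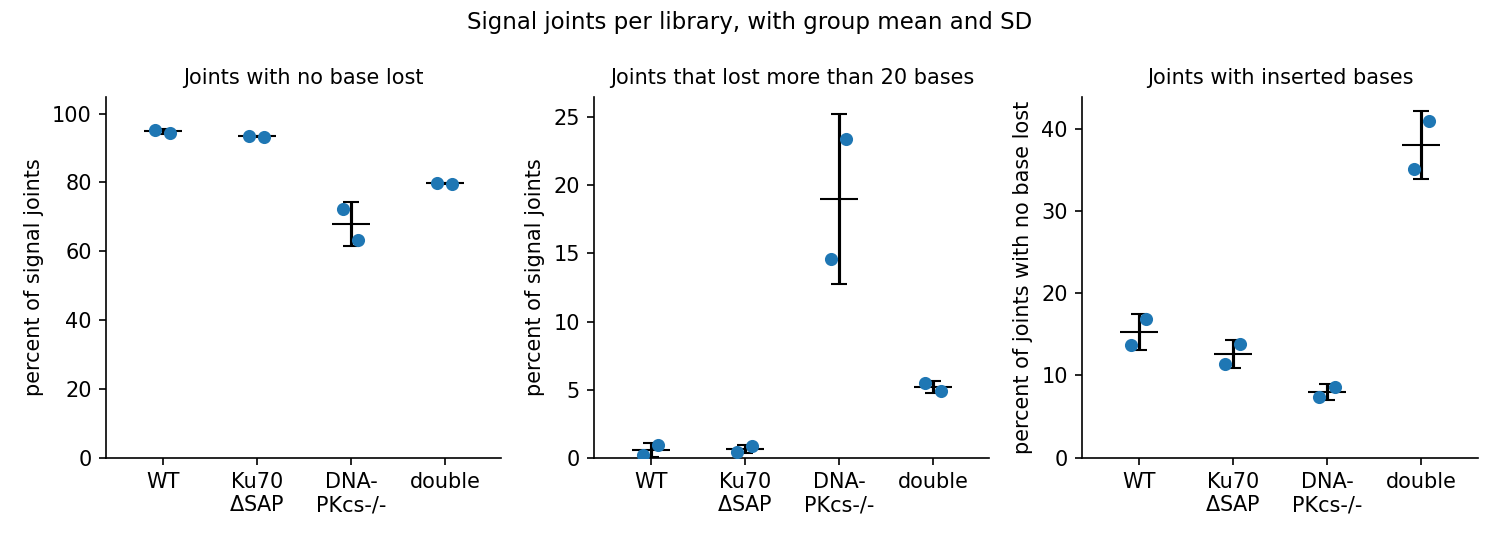
Signal joints per library. Points are libraries (2 per genotype), the horizontal mark is the group mean and the bar its SD. The first 2 vertical axes give the percent of signal joints with no base lost and the percent that lost more than 20 bases. The last gives the percent of joints with no base lost that were counted, by their alignment ends, as carrying inserted bases. Precise joints are 67.8% in DNA-PKcs−/− and 79.8% in the double mutant, and inserted bases 7.98% and 38.0%.

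In precise share, long deletions, mean loss and insertions both double-mutant libraries lay on the same side of both DNA-PKcs−/− libraries, and the exact permutation p was 0.333, the smallest possible, with adjusted p of 0.333 to 0.571. Fisher's exact test of the 4 pairs of libraries gave p from 2.77e-05 to 0.00214 for the precise share. The difference in precise share of 11.9 percentage points was 7.38 without the pooled DNA-PKcs−/− library and 5.96 with the narrow window. Over all substrate joints of both strands it was 37.3, with plus-strand joints at 45.7% of substrate junctions in DNA-PKcs−/− and 11.3% in the double mutant. It turned to -2.58 over distinct joints, where the difference in insertions was 8.53 points. That in long deletions, -13.8 points, was -6.44 with the narrow window and -26.1 over all substrate joints. The difference in mean loss of -48.7 bases was -4.06 with the narrow window, -48.3 with the wide one, -137.1 over all substrate joints, -12.0 over distinct joints, -7.46 with deletions over 200 bases left out, and -19.7 within the shared run, which leaves out the pooled DNA-PKcs−/− library. Mean loss was 48.8 bases in DNA-PKcs−/− replicate 1 and 106.9 in the pooled replicate 2, so leaving out replicate 1 widens the difference. Within the shared run the insertion share was 38.0% in the double mutant, 7.33% in DNA-PKcs−/− and 16.9% in WT.

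The effect of ΔSAP on the precise share was -1.48 percentage points with DNA-PKcs and 11.9 without it. The interaction of 13.4 points had an exact permutation p of 0.0556, the smallest of the 36 arrangements, and an adjusted p of 0.278 over 5 interactions. Libraries were exchanged within each DNA-PKcs state, so this p tests for no effect of ΔSAP in either state. It does not test whether the effects are equal, and an effect in 1 state alone could give it. The interaction was 7.60 with the narrow window, 37.8 over all substrate joints of both strands and -7.26 over distinct joints, a turn that the few positions of precise joints leave without bearing on their frequency. Leaving out a DNA-PKcs−/− library moved it to 8.85 or 18.0. For mean loss the interaction was -49.3 bases (exact permutation p = 0.111, adjusted p = 0.278), -5.55 with the narrow window and -52.0 with the wide one (exact permutation p = 0.0556 for each), -145.4 over all substrate joints, -7.45 with deletions over 200 bases left out and -4.27 over distinct joints.

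In activated splenic B cells, the comparison of ΔSAP with WT asks whether the SAP deletion alters the place and structure of class switch junctions. Shares of recovered junctions do not measure how much switching took place. Junctions fell mainly in Sγ1, 61.4% ± 0.488 in WT (SD, n = 2) and 57.3% ± 3.36 in ΔSAP (SD, n = 3). Sμ held 19.9% ± 0.396 and 18.9% ± 0.386, and 5.89% ± 0.814 and 5.91% ± 0.659 lay outside IgH. Sε, the switch region of IgE, held 10.9% ± 0.884 of WT junctions and 16.0% ± 2.67 of ΔSAP junctions, and all 3 ΔSAP libraries (13.4% to 18.8%) lay above both WT libraries (10.2% and 11.5%). Junction structure was close in each region: microhomology marked 55.9% ± 0.245 of Sγ1 junctions in WT and 54.8% ± 1.11 in ΔSAP, and 53.8% ± 2.27 and 53.7% ± 0.521 of Sε junctions. Insertions marked 20.2% ± 0.716 and 20.3% ± 0.442 of Sγ1 junctions.

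For Sε the exact permutation p was 0.2, with an adjusted p of 0.556, and 2 libraries against 3 cannot go below 0.1. The Sγ1 difference of -4.06 percentage points was -2.14 without the pooled ΔSAP library and -6.82 with Sγ1 and Sε junctions alone as the denominator, and that in Sγ1 microhomology, -1.15, was -0.511 without ΔSAP replicate 1. Among Sε junctions 5.57% ± 0.395 were distal in ΔSAP and 4.48% ± 0.566 in WT, and 5.50% ± 0.391 against 6.87% ± 0.260 lay on the plus strand, the inversional orientation. Both differences had an exact permutation p of 0.1 and an adjusted p of 0.4, and the latter was -0.689 in place of -1.37 with the region 2 kb narrower. All 5 libraries carried the same run tag.

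**Figure D2:**
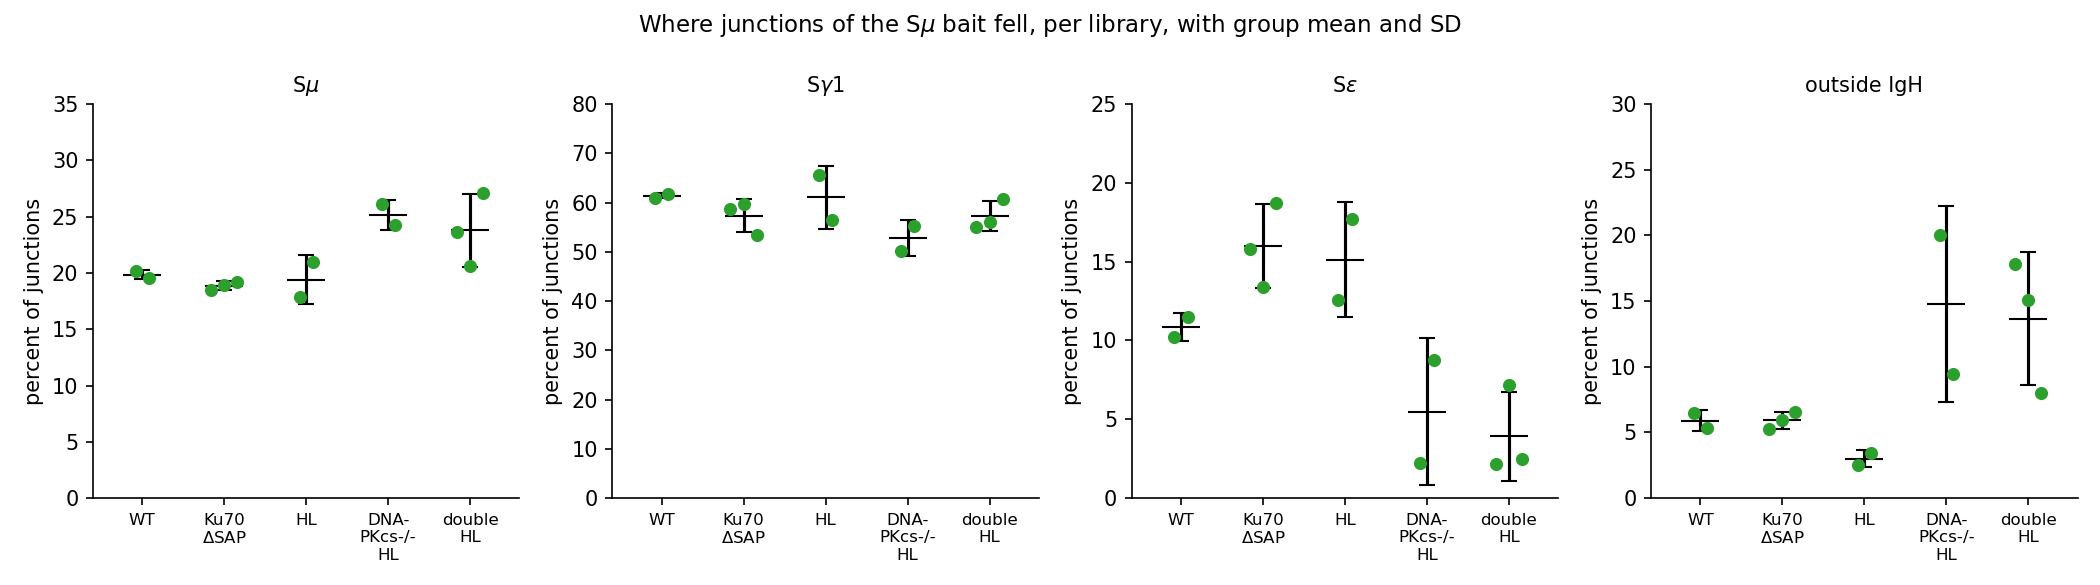
Share of junctions from the Sμ bait in Sμ, Sγ1, Sε and outside IgH. Points are libraries (2 or 3 per genotype), the horizontal mark is the group mean and the bar its SD; the vertical axes give the percent of all junctions of a library. Sε holds 15.1% in HL, 5.49% in DNA-PKcs−/− HL and 3.93% in double-mutant HL.

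On the HL background, the comparison of the 5 DNA-PKcs-deficient libraries with the 2 HL libraries asks what DNA-PKcs contributes to class switch junctions. Of the 5, 2 are DNA-PKcs−/− HL and 3 are double-mutant HL. The series has no ΔSAP HL group with DNA-PKcs, so this comparison does not set the SAP deletion apart. Microhomology was more frequent in all 3 switch regions: 71.2% ± 1.66 of Sγ1 junctions against 54.9% ± 1.95, 68.9% ± 1.58 of Sμ junctions against 50.6% ± 2.07, and 69.3% ± 4.44 of Sε junctions against 51.7% ± 1.45 (SD, n = 5 and n = 2). Insertions were less frequent, 11.1% ± 1.33 against 21.5% ± 0.641 in Sγ1 and 18.3% ± 1.68 against 27.5% ± 1.27 in Sμ. Sε held 4.56% ± 3.18 of junctions against 15.1% ± 3.62, and sequence outside IgH 14.1% ± 5.21 against 3.01% ± 0.640. Within Sμ, the distal share was 11.8% ± 2.71 against 2.56% ± 0.581, and the share on the plus strand 32.3% ± 2.50 against 25.9% ± 1.35. The Sμ distal share of the proficient groups without the HL alleles was also above HL, at 8.54% ± 0.502 in WT and 8.72% ± 0.290 in ΔSAP. That difference therefore cannot be laid to DNA-PKcs alone. All 5 deficient libraries lay beyond both HL libraries in every measure of this paragraph.

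**Figure D3:**
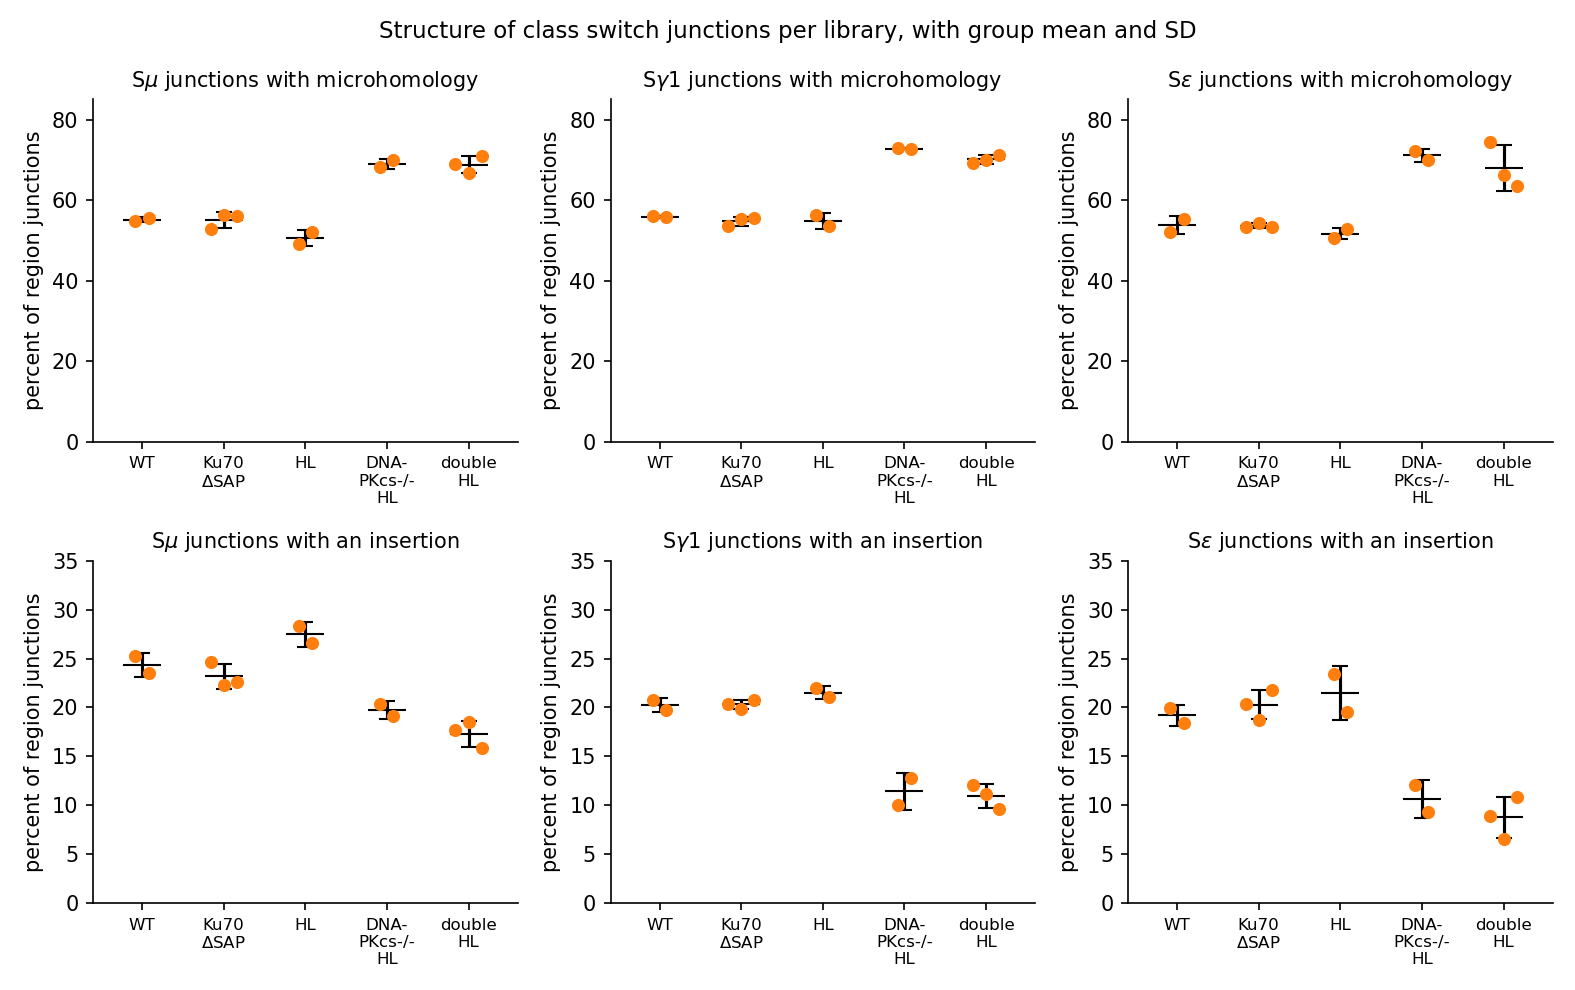
Structure of class switch junctions in Sμ, Sγ1 and Sε. Points are libraries (2 or 3 per genotype), the horizontal mark is the group mean and the bar its SD; the vertical axes give the percent of the junctions of a region with microhomology (upper row) or with an insertion (lower row). In Sγ1, microhomology is 54.9% in HL, 72.8% in DNA-PKcs−/− HL and 70.1% in double-mutant HL.

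The exact permutation p was 0.0476, the smallest that 5 libraries against 2 allow, for the Sε share, for microhomology and insertion in each region and for the distal and plus-strand shares of Sμ, and 0.0952 for the share outside IgH. Adjusted p lay at 0.245 for structure, 0.4 for position and 0.556 for region shares. The Sγ1 share was 55.5% ± 3.79 against 61.0% ± 6.38, a difference of -5.54 percentage points that turned to 1.71 with IgH junctions as the denominator and to 12.6 with Sγ1 and Sε junctions alone. Each DNA-PKcs-deficient genotype also differed from HL on its own, Sγ1 microhomology by 18.0 points in DNA-PKcs−/− HL (exact permutation p = 0.333, the smallest possible) and by 15.3 points in double-mutant HL (exact permutation p = 0.1, also the smallest).

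The last comparison asks what the SAP deletion adds to the loss of DNA-PKcs in class switch junctions. Double-mutant and DNA-PKcs−/− libraries overlapped in the shares of Sμ (23.8% ± 3.25 and 25.2% ± 1.32), Sε (3.93% ± 2.82 and 5.49% ± 4.64) and sequence outside IgH (13.7% ± 5.07 and 14.8% ± 7.46). Sγ1 held 57.3% ± 3.05 and 52.7% ± 3.67. Sγ1 microhomology was 70.1% ± 1.07 in the double mutant and 72.8% ± 0.0886 in DNA-PKcs−/− (SD, n = 3 and n = 2), with all 3 double-mutant libraries below both others, and Sμ insertions were 17.3% ± 1.33 and 19.7% ± 0.924. Direct joins of Sγ1 made up 18.9% ± 0.191 and 15.7% ± 1.81. With 1 library left out, the Sγ1 difference of 4.59 points lay between 1.99 and 7.19, that outside IgH between -6.38 and 4.17, that of Sε (-1.56) between -4.84 and 1.72 and that of Sμ (-1.36) between -3.02 and 0.228. The difference in Sμ insertions of -2.40 points was -0.346 with insertions over 10 bases left out.

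Over both DNA-PKcs states, ΔSAP libraries were below their controls in Sγ1 microhomology by a mean of -1.92 percentage points, 6 of 6 ΔSAP libraries lying below both controls of their DNA-PKcs state (exact permutation p = 0.03, adjusted p = 0.245). No interaction of ΔSAP with DNA-PKcs passed in microhomology by the same test within each state, with exact permutation p of 0.4 in Sγ1, 1 in Sμ and 0.51 in Sε. The HL alleles change together with DNA-PKcs between these strata, and the strata carried different run tags.

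The bait sequence of Sε junctions carried 26.2 ± 2.69 mismatches per 10000 bases in HL (SD, n = 2), 13.1 ± 2.44 in DNA-PKcs−/− HL (SD, n = 2) and 18.4 ± 7.99 in double-mutant HL (SD, n = 3). In the bait of junctions to other IgH sequence the rate was 32.7 ± 3.64 in WT, 53.8 ± 20.4 in ΔSAP, 57.1 in the 1 HL library with such a list, 12.9 ± 9.04 in DNA-PKcs−/− HL and 6.65 ± 2.87 in double-mutant HL. The difference between ΔSAP and WT was 21.03, and 10.1 without the pooled ΔSAP library. The share of these reads with any mismatch was 14.1% and 14.7% in the WT libraries and 13.7% to 16.5% in the ΔSAP libraries. The lowest adjusted p of the 7 comparisons was 0.52 by the exact permutation test. Between 5 and 68 mismatched bases per library stand behind the Sε rates on the HL background, and the other IgH rates rest on 7 and 4 such bases in DNA-PKcs−/− HL and on 2, 2 and 1 in double-mutant HL.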

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

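All tests of explanations in this part were chosen after the result was seen, except the one on copied inserted sequences. Nothing here separates genotype from everything else that differs between 2 libraries of a group, and a genotype effect stays open as a hypothesis throughout.

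The precise share of signal joints was lower in ΔSAP than in WT but higher in the double mutant than in DNA-PKcs−/−, a difference between groups of 13.4 percentage points (exact permutation p = 0.0556, adjusted p = 0.278). As above, that p tests for no effect of ΔSAP in either DNA-PKcs state. Over distinct joints both directions turned, to 4.68 and -2.58, and the difference to -7.26, but precise joints hold only 4 to 18 positions per library, so this count does not bear on how frequent they are. For the lower share of long deletions in the double mutant, counting error in the few DNA-PKcs−/− signal joints would leave at least 1 pair of libraries alike. The largest Fisher's exact p of the 4 pairs was 5.76e-09. That test counts each joint read as a separate event, and the 377 and 128 DNA-PKcs−/− joints held only 82 and 38 distinct joints. It therefore cannot exclude error in the number of separate joining events, which PCR copies may hide. A sequencing run could not be told apart from genotype, since the difference was -9.42 percentage points within the shared run but rested on 1 DNA-PKcs−/− library. A like number of long joints per sequenced junction, diluted by more intact joints in the double mutant, could not be told apart either: the difference was -12.1 per 1000 junctions, with DNA-PKcs−/− libraries at 9.94 and 44.2 and double-mutant libraries at 14.1 and 15.8.

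Data outside the main comparisons of the report held a signal above both WT libraries. Substrate joints on the plus strand, opposite to the inversional signal joint, were 45.7% ± 1.48 of substrate junctions in DNA-PKcs−/− and 11.3% ± 0.268 in the double mutant, against 2.85% ± 0.162 in WT (SD, n = 2 each). Junctions off the substrate were 66.6% ± 25.1 and 64.3% ± 0.0236 of all junctions, against 15.8% ± 2.79 in WT.

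A fixed background of plus-strand joints per sequenced junction would give overlapping rates. Per 100 junctions they were 2.25 to 2.58 in proficient libraries, 3.98 and 4.12 in the double mutant and 7.32 and 22.8 in DNA-PKcs−/−. The lowest deficient library thus lay 1.40 per 100 junctions above the highest proficient one, which argues against a rate common to all libraries. PCR copies are counted and both double-mutant libraries shared a run tag, so a background that differs between libraries is not excluded. Loss of signal joints alone would leave plus-strand joints at the proficient level of 12.6 to 27.7 per 100 off-substrate junctions. The mean was 27.7 in DNA-PKcs−/−, where the libraries at 8.68 and 46.7 could not be told apart from that level or from a genotype effect. In the double mutant it was 6.30, below that level, where off-substrate junctions were also more frequent, so this explanation could not be told apart there either.

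Insertions in double-mutant signal joints could come from a sequencing run, but within the shared run the lowest double-mutant library lay 18.2 percentage points above the highest other library. This argues against an effect common to the whole run, but rests on 1 WT and 1 DNA-PKcs−/− library there. A few inserted sequences copied many times could not be told apart from many separate events. The most frequent sequence was 12.1% of the 232 inserts read, out of 594 joints counted as carrying an insertion. The list covers 1 double-mutant library.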

How the results depend on the processing

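With these numbers of libraries no group comparison could pass after adjustment, so staying on the same side of the threshold carries no information, and the alternatives are read by direction and size. Of 527 values under alternatives that keep all libraries, 484 kept their sign, 38 changed it and 5 were 0; with 1 library left out, 748 of 819 kept their sign and 71 changed it. Both bait windows, the authors' deletion lists, and the interaction under other choices of joints were chosen after seeing the data. Where a direction turned the cause was not tested. Distinct precise joints number only 4 to 18 per library, so the precise and insertion shares over distinct joints do not measure how frequent such joints are. The smallest signal joint library holds 128 joints. Not run for want of the needed columns were microhomology at signal joints, the inserted length in the rule for distinct joints, each distinct class switch junction once, and wider regions and other IgH mismatches for HL replicate 2. The block was left out for bait mismatches and interactions, and pooling for bait mismatches.

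With each distinct signal joint counted once, ΔSAP minus WT turned to 4.68 (precise share), -7.72 (mean loss), -4.55 (mean loss of joints with a loss), -8.12 (long deletions) and 2.96 (insertions), double mutant minus DNA-PKcs−/− to -2.58 (precise share), deficient minus proficient to -8.18 (insertions), and the interaction to -7.26 (precise share). With deletions over 200 bases left out ΔSAP minus WT turned to -0.00728 (mean loss) and -1.55 (joints with a loss), and with all substrate joints to -1.08 (long deletions). With the narrow window the ΔSAP effect over both DNA-PKcs states turned to 3.63 (mean loss of joints with a loss).

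With IgH junctions as denominator, double-mutant HL minus HL turned to 3.50 (Sγ1) and 0.0296 (other IgH) and all deficient minus HL to 1.71 (Sγ1). With Sγ1 and Sε junctions alone the Sγ1 share turned to 11.0, 13.6 and 12.6 for DNA-PKcs−/−, double-mutant and all deficient minus HL, and to -2.10 for ΔSAP over both states. With insertions over 10 bases left out ΔSAP minus WT turned to -0.192 (Sγ1 insertion) and 0.0982 (Sε microhomology). With microhomology from 2 bases double-mutant minus DNA-PKcs−/− turned to 0.0798 (Sε). With regions 2 kb narrower it turned to 0.0559 (Sμ distal), and ΔSAP over both states to 0.0603 (Sμ distal) and 0.0248 (Sε plus strand); 2 kb wider, to 0.0125 (Sμ distal). With pooled libraries ΔSAP minus WT was -0.0423 (outside IgH), double mutant minus DNA-PKcs−/− -1.09 (Sε plus strand) and ΔSAP over both states -0.485 (Sε distal).

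The labels do not say that a replicate number marks anything shared. Deviations of same-numbered libraries correlated from 0.581 to 0.957 over 6 pairs of signal joint groups and from -0.335 to 0.531 over 10 pairs of class switch groups. The signal joint values include the most frequent joint, which held 47.1% to 82.9% of a library. In every group its share was higher in replicate 1 than in replicate 2, so that joint alone may carry these correlations. They were not computed without it. With the replicate number as a block, p could not go below 0.5 for 1 genotype against 1, 0.125 over both states, or 0.0556 and 0.111 for all deficient libraries in the 2 assays, so no call could appear, and none of the latter turned. The share outside IgH turned to -0.292 (ΔSAP minus WT), 1.72 (double mutant minus DNA-PKcs−/−) and 0.713 (both states), Sγ1 insertion to -0.127, 0.209 and 0.0409, Sε microhomology to 0.0765 (ΔSAP minus WT), Sμ plus strand to 0.128 (double mutant minus DNA-PKcs−/−) and Sε distal to -1.18 (both states).

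With 1 library left out, ΔSAP minus WT ran from -0.554 to 0.598 (outside IgH), -0.785 to 1.01 (Sμ microhomology), -0.426 to 0.586 (Sγ1 insertion), -1.67 to 1.53 (Sε microhomology) -0.00163 to 0.0823 (Sγ1 distal), -0.568 to 1.64 (mean loss), -16.4 to 21.6 (joints with a loss), -0.252 to 0.449 (long deletions), -0.213 to 0.0146 (other IgH), -0.182 to 0.528 (Sμ distal) and -2.42 to 0.938 (Sμ plus strand). ΔSAP over both states ran from -1.03 to 1.57 (Sγ1), -3.18 to 2.10 (outside IgH), -0.676 to 0.402 (Sμ microhomology), -0.866 to 0.477 (Sγ1 insertion), -1.09 to 0.297 (Sε insertion), -0.970 to 0.824 (Sμ distal), -1.09 to 1.52 (Sε distal) and -1.11 to 0.975 (Sε plus strand). Double-mutant HL minus HL ran from -8.21 to 0.809 (Sγ1) and -0.278 to 0.00305 (other IgH), and all deficient minus HL from -10.05 to -1.03 (Sγ1), -0.0622 to 0.224 (other IgH) and -3.20 to -1.36 (Sγ1 plus strand). Double mutant minus DNA-PKcs−/− ran from -3.02 to 0.228 (Sμ), -6.38 to 4.17 (outside IgH), -4.84 to 1.72 (Sε), -1.22 to 0.848 (Sμ microhomology), -1.81 to 0.875 (Sγ1 insertion), -2.11 to 1.47 (Sμ distal), -2.86 to 0.128 (Sμ plus strand), -3.27 to 1.94 (Sε distal), -0.837 to 3.32 (Sε plus strand) and -12.6 to 0.191 (other IgH mismatches). The interaction ran from 8.85 to 18.0 (precise share), -78.3 to -20.2 (mean loss) and -1.22 to 0.984 (Sμ microhomology).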

Other observations

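Inserted bases at otherwise precise signal joints could be read in 1 WT and 1 double-mutant library, and there only for joints whose alignments stop at both signal ends. The lists cover 598 of 1887 WT joints counted as carrying an insertion and 232 of 594 double-mutant ones. The 598 WT inserts held 110 distinct sequences with a mean length of 2.68 bases, 52.8% G or C, and GA was the most frequent (59 inserts). The 232 double-mutant inserts held 90 distinct sequences with a mean length of 3.28 bases, 69.3% G or C, and GC was the most frequent (28 inserts). Inserts of at most 4 bases were 90.5% in WT and 77.2% in the double mutant.

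Longer microhomology was also more frequent at class switch junctions without DNA-PKcs. Overlaps of 4 bases or more marked 25.2% ± 2.30 of Sγ1 junctions in DNA-PKcs−/− HL (SD, n = 2) and 23.2% ± 0.913 in double-mutant HL (SD, n = 3), against 10.4% ± 1.60 in HL (SD, n = 2). In Sμ the shares were 20.9% ± 1.25 and 19.8% ± 0.516, against 11.3% ± 0.00849 in HL, and in Sε they were 13.0% ± 3.03 and 13.3% ± 2.38, against 8.00% ± 0.117. In WT they were 10.6% in Sγ1, 12.8% in Sμ and 8.65% in Sε.

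Some minus-strand joints had a bait end below the wide window and a prey position at or past the prey signal end. They were 10.6% ± 6.46 of minus-strand joints in WT, 8.44% ± 0.989 in ΔSAP, 8.55% ± 7.80 in DNA-PKcs−/− and 1.19% ± 0.352 in the double mutant (SD, n = 2 each). No upper limit was set on the prey position, so joints that do not use the cut signal end may be among them.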
